A study of Arabidopsis thaliana with 12 samples.

How the data were processed

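Total RNA from whole seedlings was labelled with biotin by the submitters from 5 ug per sample and hybridised to 12 one-colour Affymetrix-type arrays, 3 biological replicates for each of 4 groups (WT and pft1-1 at 16C and 23C, 80 micromoles per second and square metre of continuous light). The deposited table holds 1 value per probe set and array in log2 units, which the authors had normalised between arrays and summarised per probe set. The submitters' processing notes name RMA and affy without versions. The values ran from 1.59 to 15.2 with nearly equal quartiles on all arrays. The raw scans, the probe definition and the date of each hybridisation are not given in the sources used here.

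The table holds 22810 probe sets. The 64 control probe sets were set aside for quality measures, and 22746 were tested without a filter on low values. Gene names came from the annotation supplied with the series, matched by Entrez identifier to a gene table. Of the probe sets tested 13513 had 1 gene, 503 several and 8730 none, and 13356 distinct genes were named. PFT1 and most flowering genes had no named probe set. Identical values were found in 0 pairs of arrays.

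Before the data were examined, the groups, the comparisons, the tests, the alternatives, 23 gene lists, 16 phrases for gene families and the rule for naming genes were fixed. The lists covered flowering promoters and repressors, Mediator subunits, jasmonate synthesis and response, jasmonate-ethylene and salicylate defence, cold, heat shock, iron deficiency, shade and warm-temperature elongation, flavonoid and anthocyanin synthesis, abscisic acid and drought, the clock, photosynthesis, root hairs, glucosinolates, the cell cycle, ethylene, gibberellin, floral organs, roots, seed storage and reference genes. The annotation named 63 of their 420 members, after 9 whose identifier and symbol disagreed were dropped. The lists for abscisic acid and drought, the clock, floral organs and seed storage had 0 measured members and gave no result. Families were searched in gene symbols and synonyms, since the gene table has no descriptions. Lists with at least 3 members and families with 5 to 500 were tested, 20 sets in all. Another 26 families were formed from gene symbols and organelle genes after the annotation had been seen, and were tested in a family of their own.

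Each probe set was fitted in limma 3.58.1 under R 4.3.3 with the means of the 4 groups on all 12 arrays and a shared residual variance (lmFit and eBayes, 8 residual and 1.05 prior degrees of freedom). A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 over all 22746. With no change at all, chance gives an unadjusted p under 0.05 for a share of about 0.05 of the probe sets. Comparisons were pft1-1 minus WT at 23C, at 16C and averaged over both, 23C minus 16C in WT and in pft1-1, and the interaction. SE is the moderated standard error from limma. Gene sets were tested with camera at a preset correlation of 0.01 on 1 probe set per gene, adjusted over the 20 sets, and again with an estimated correlation and with fry. Counts adjusted over the list alone used Benjamini-Hochberg within each list. They were not adjusted over the lists or the comparisons, so single members can pass by chance. Overlaps were compared with the product of the counts over the number tested. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

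The naming rule took PFT1, CO, FT, TSF, SOC1, FLC, SVP, GI and TEM1 whatever their test. It took the 12 largest rises and 12 largest falls among called probe sets with 1 gene and groups that do not overlap, in each genotype comparison and in WT by temperature. For the other comparisons it took 5 and 5, and from each list up to 4 called members. The text gives some of the larger ones among these, and names outside the rule are said to be so.

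Alternatives were the replicate letters as a block, an intensity trend, only the arrays compared, the upper 60% of probe sets by mean, renewed quantile normalisation, centring on array medians, array quality weights, a log2 change of at least 1, an adjusted p under 0.01, 1 probe set per gene and leaving out each array. Letter C as a block, letters A and B alone and an additive fit on letter C alone were added after seeing the data. The letters come from the sample titles, and the submitters state that RNA was prepared independently. Whether letters pair arrays was checked by correlating residuals of arrays that share a letter. All 3 correlations passed 0.1 for pft1-1 minus WT at 23C (0.129, 0.473 and 0.158), for temperature in WT (0.421, 0.274 and 0.529) and in pft1-1 (0.200, 0.196 and 0.339), but not at 16C between genotypes (0.357, -0.101 and 0.474).

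The procedure was tested on simulated data with independent normal noise, sized by the residual standard deviation of each probe set. The simulation held no letter effect, no correlation between genes, no unequal arrays and no background floor. A change of 2 on the log2 scale was recovered in 74% to 90% of probe sets and a change of 1 in 36% to 77%. There were 5 to 17 false calls among 22746. These rates apply to such noise and may not hold for the real arrays. Precision is limited by the 3 arrays per group, and a probe set near background cannot show a fall.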

Results

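Gene expression was measured in whole Arabidopsis thaliana seedlings with 12 one-colour arrays, 1 array per biological replicate. The seedlings were 10 days old and belonged to 4 groups of 3 replicates: the wild type Columbia (WT) and the mutant pft1-1, each grown at 16C and at 23C in continuous light. The mutant is affected in PFT1, also called MED25, a part of Mediator, the complex that links transcription factors to RNA polymerase. Replicates carry the letters A, B and C in each group. The values are log2 expression per probe set, and 22746 probe sets were tested after 64 control probe sets were set aside. Array medians ran from 5.07 to 5.25, and the number of arrays limits the precision. Of the probe sets tested, 13513 (59.4%) carried 1 gene in the annotation used, and PFT1 itself had no named probe set there, so its level was not analysed here.

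The 4 arrays of letter C stood apart from the 8 arrays of letters A and B. Poly-A spike-in probe sets averaged 2.45 to 2.54 on a log2 scale on the arrays of letters A and B and 4.84 to 9.51 on those of letter C. The 3' minus 5' difference of the Arabidopsis control transcripts, a sign of RNA or labelling quality, ran from 2.64 to 3.07 in letters A and B and from 3.52 to 4.53 in letter C, a difference of means of 1.11 (exact permutation test, two-sided, p = 0.00202, the smallest it can give). Every group holds 1 letter C array. Between groups, pft1-1 minus WT of the control difference was 0.22 at 23C (exact permutation p = 0.7) and -0.22 at 16C (exact permutation p = 0.5), and 23C minus 16C was -0.04 in WT (exact permutation p = 0.8) and 0.40 in pft1-1 (exact permutation p = 0.5). These 4 two-sided tests had a Benjamini-Hochberg adjusted p of 0.8 each, and 3 arrays against 3 cannot go below 0.1. Within letters A, B and C, pft1-1 minus WT was -0.15, -0.41 and -0.10 at 16C, and 23C minus 16C was 0.17, 0.03 and 1.01 in pft1-1, 1 sign in all 3 letters (exact sign-flip test, p = 0.25 each, the smallest it can give). It was 0.08, -0.07 and 0.67 for pft1-1 minus WT at 23C (exact sign-flip p = 0.5) and -0.06, -0.30 and 0.25 for temperature in WT (exact sign-flip p = 0.75). With a single array per group, letter C alone allows no test between 2 groups. An additive fit of genotype and temperature on these 4 arrays, with 1 residual degree of freedom, called 0 probe sets in limma for genotype (976 with an unadjusted p under 0.05) and 0 for temperature (2765 with an unadjusted p under 0.05). Values from letters A and B alone and from a model with letter C as a block stand beside the results.

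**Figure D1:**
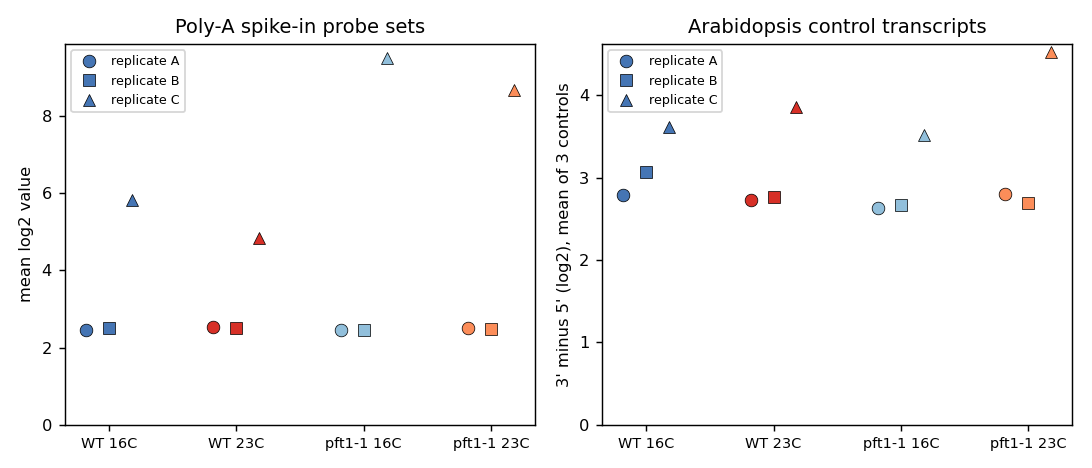
The left panel shows the mean log2 value of the poly-A spike-in probe sets, and the right panel the 3' minus 5' difference (log2) of the Arabidopsis control transcripts, averaged over 3 controls. Each point is 1 of the 12 arrays, with the group on the horizontal axis and the replicate letter as the symbol. Letter C lies highest in every group, from 4.84 to 9.51 on the left and from 3.52 to 4.53 on the right.

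The comparison of pft1-1 with WT at 23C asked which transcripts differ between the mutant and WT at the warmer temperature. With a single mutant line, an effect of PFT1 cannot be told apart from other differences between the lines. The plant defensin genes PDF1.2 and PDF1.2b, antifungal peptide genes known to respond to jasmonate and ethylene, fell in pft1-1. PDF1.2 averaged 9.41 ± 1.23 (SD, n = 3) in WT and 3.77 ± 0.61 (SD, n = 3) in pft1-1, a log2 change of -5.64 (SE 0.63, limma adjusted p = 0.040). PDF1.2b averaged 9.99 ± 1.16 (SD, n = 3) in WT and 3.06 ± 0.31 (SD, n = 3) in pft1-1, a log2 change of -6.92 (SE 0.71, limma adjusted p = 0.031). Its probe set is of the type that can also bind related transcripts. AT1G43590 fell by 2.83 (SE 0.21, limma adjusted p = 0.0034), from 5.73 to 2.91. Among probe sets without a gene in the annotation used, singled out after their values were seen, 255725_at rose by 3.79 (SE 0.22, limma adjusted p = 0.00073) and 258791_at fell by 3.07 (SE 0.33, limma adjusted p = 0.040). These were the 5 probe sets called, 1 up and 4 down. For each of them all 3 pft1-1 arrays lay on 1 side of all 3 WT arrays.

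Of the gene groups fixed in advance, 5 ranked low against other genes in pft1-1 at 23C with the preset correlation and 0 with an estimated correlation. Tested against no change, with fry, 1 of these passed, jasmonate-ethylene defence (adjusted p = 0.0033). Of the 4 measured jasmonate-ethylene defence genes, 2 fell over all probe sets and 2 adjusted over the list alone, the defensins named above. The others were OSM34, an osmotin-like gene, at -0.90 (SE 0.43) and PDF1.1, listed as LCR67, at 0.04 (SE 0.21). The list ranked low against other genes (camera adjusted p = 8.2e-06, and adjusted p = 0.0934 with an estimated correlation). Its calls came from the 2 related defensins, whose probe sets may bind the same transcripts and so may not be independent members. The 3 measured glucosinolate synthesis genes, which belong to a sulfur-rich defence pathway, had log2 changes of -3.62 (SE 0.88) for BCAT4, -1.35 (SE 0.39) for UGT74B1 and -1.72 (SE 0.68) for GSTU20. None passed over all probe sets and 3 fell adjusted over the list alone (camera adjusted p = 0.00016, and adjusted p = 0.204 with an estimated correlation). Of the 9 peroxidase genes, 0 were called over all probe sets and 2 fell adjusted over the list alone (camera adjusted p = 0.033, and adjusted p = 0.204 with an estimated correlation). The 3 cell cycle genes (camera adjusted p = 0.014, and adjusted p = 0.422 with an estimated correlation) and the 5 flavonoid and anthocyanin genes (camera adjusted p = 0.033, and adjusted p = 0.559 with an estimated correlation) had negative changes throughout, with 0 called over all probe sets or over the list alone. The directions held with arrays quantile normalised again or centred on their medians. In letters A and B alone the camera adjusted p was 0.000434 for the jasmonate-ethylene list, 0.0345 for glucosinolates, 0.162 for peroxidases, 0.233 for the cell cycle and 0.346 for flavonoids. With letter C as a block the flavonoid list had an adjusted p of 0.0686, and with the letters as replicate block 0.105. In that list DFR and UF3GT stood at 2.49 and 2.42 on replicate A of WT at 23C. The pft1-1 arrays at 23C gave 2.43 to 2.49 and 2.40 to 2.57, near background. The lower means of these genes in pft1-1 thus came from replicates B and C of WT.

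The calls at 23C were few. With the letters as replicate block, 4 probe sets were called, and PDF1.2b (limma adjusted p = 0.147), PDF1.2 (limma adjusted p = 0.170) and 258791_at (limma adjusted p = 0.163) were no longer among them. With letter C as a block 2 were called, with adjusted p of 0.0697 for PDF1.2b, 0.0971 for PDF1.2 and 0.0886 for 258791_at. In letters A and B alone 2 were called, among them 255725_at (limma adjusted p = 0.029), with 0.434 for PDF1.2b, 0.493 for PDF1.2, 0.292 for AT1G43590 and 0.453 for 258791_at. With only the 6 arrays of 23C 0 were called in limma, while 1729 had an unadjusted p under 0.05 in the full model. The count was 2 without replicate B or C of WT at 16C, 2 without replicate B of pft1-1 at 16C, 2 without replicate A of pft1-1 at 23C and 3 without its replicate C. It was 20 without replicate A of WT at 23C and 54 without replicate B of pft1-1 at 23C. PDF1.2 lost its call without any 1 of 9 arrays, with adjusted p up to 0.142 (without replicate C of pft1-1 at 23C), PDF1.2b without any 1 of 7, with adjusted p up to 0.119 (without the same array), and 258791_at without any 1 of 9, with adjusted p up to 0.138 (without replicate C of WT at 23C). AT1G43590 and 255725_at kept theirs without any single array. The cell cycle list had an adjusted p of 0.105 without replicate C of WT at 23C, 0.0705 without replicate A and 0.0653 without replicate C of pft1-1 at 23C. The peroxidase list had 0.177 without replicate B of WT at 23C, 0.144 without replicate A and 0.124 without replicate C of pft1-1 at 23C. The flavonoid list had 0.195 and 0.110 without replicates B and C of WT at 23C, and 0.0705, 0.0807 and 0.220 without replicates A, B and C of pft1-1 at 23C. Groups of 3 arrays did not overlap for 7.95% of probe sets, where chance gives 10%.

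**Figure D2:**
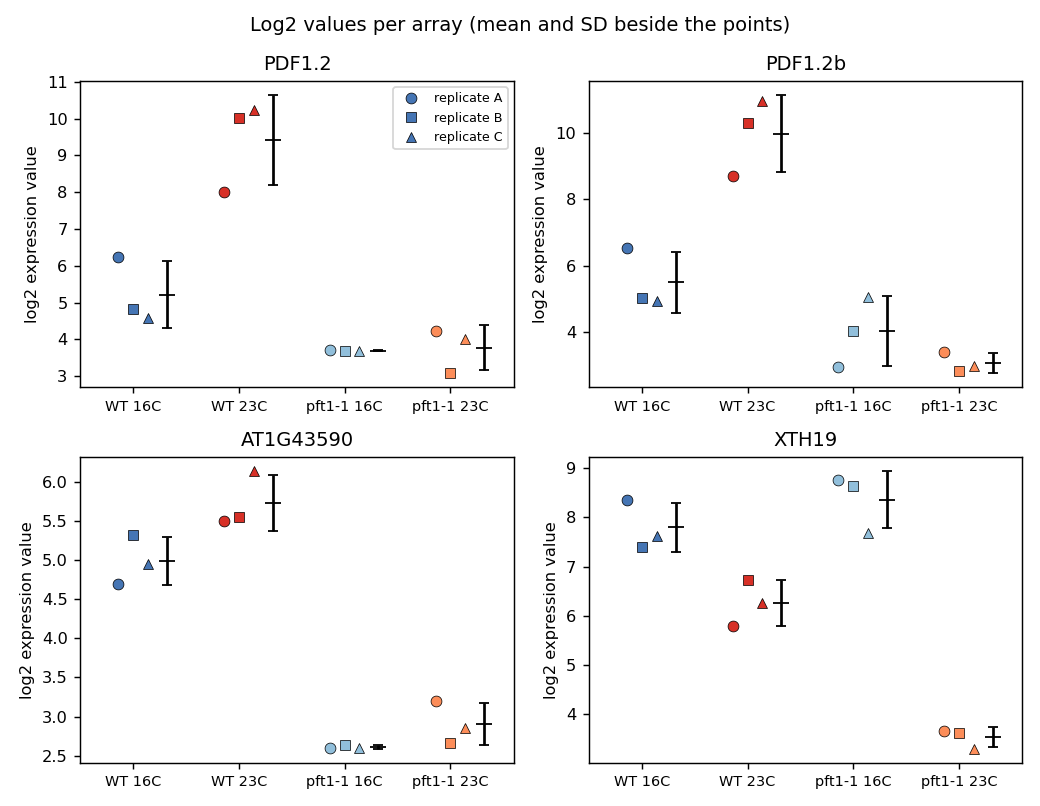
Each panel shows the log2 expression value of 1 gene on the 12 arrays, with the group on the horizontal axis, the replicate letter as the symbol, and the group mean with 1 SD (n = 3) beside the points. PDF1.2, PDF1.2b and AT1G43590 were chosen as genes called at 23C and XTH19 as a cell wall gene called in both temperature comparisons, after their values were seen. PDF1.2 averaged 9.41 in WT at 23C and 3.70 to 5.22 in the other groups.

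At 16C the comparison of pft1-1 with WT asked the same question at the cooler temperature. AT5G33370, of the GDSL lipase family, fell by 3.11 (SE 0.34, limma adjusted p = 0.023), and AT1G43590 fell by 2.38 (SE 0.21, limma adjusted p = 0.0098). AT5G55720 (-1.51, SE 0.12, limma adjusted p = 0.0043) and AT4G15120 (-0.37, SE 0.05, limma adjusted p = 0.045) fell as well. AT1G49570 rose by 2.30 (SE 0.23, limma adjusted p = 0.017), AT5G52790 by 1.31 (SE 0.14, limma adjusted p = 0.023) and AT5G16230 by 0.68 (SE 0.07, limma adjusted p = 0.023). The unnamed 255725_at, singled out after its values were seen, rose by 4.07 (SE 0.22, limma adjusted p = 0.00039). PDF1.2 and PDF1.2b had log2 changes of -1.52 (SE 0.63) and -1.48 (SE 0.71), and neither passed. In total 8 probe sets were called, 4 up and 4 down, with 3 arrays per group that did not overlap in any of the 8. For AT1G49570, AT5G52790, AT5G16230, AT5G33370 and AT4G15120 at least 1 group mean lay under 2.52, the lower quartile of all values, near background. The rises of AT1G49570 and AT5G52790, which averaged under 2.52 in WT, and the fall of AT4G15120, which did so in pft1-1, are therefore lower bounds.

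Among the gene groups, the 12 measured glutathione S-transferase genes, which encode detoxification enzymes, were higher in pft1-1 at 16C against other genes (median log2 change 0.47, 8 positive and 4 negative, camera adjusted p = 0.019, and adjusted p = 0.564 with an estimated correlation). None of them was called over all probe sets, and 1 rose adjusted over the list alone. With the arrays quantile normalised again 3 members were negative. The list had an adjusted p of 0.423 and 0.0801 without replicates B and C of WT at 16C, and 0.327 and 0.0636 without replicates A and B of pft1-1 at 16C. With letter C as a block it was 0.012, and in letters A and B alone 0.00046. Adjusted over each list alone, 1 cold-responsive gene and 1 xyloglucan endotransglucosylase gene rose, and 1 peroxidase gene rose and 1 fell. The terpene synthase list had 1 measured gene, which was lower at an unadjusted p under 0.05 in limma, as a list of 1 leaves nothing to adjust.

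With letter C as a block 12 probe sets were called at 16C, in letters A and B alone 1, the unnamed 255725_at (limma adjusted p = 0.037), and with only the 6 arrays of 16C 0 in limma. In the full model 1052 of 22746 had an unadjusted p under 0.05, below the share of 0.05 that chance gives. Array quality weights gave 216 calls, an intensity trend in the variance 15 and centring on array medians 14. The count was 23, 30 and 42 without replicates A, B and C of pft1-1 at 16C, 4 and 3 without replicates B and C of WT at 23C, and 3 without replicate A or B of pft1-1 at 23C. Of the genes named, AT1G49570 lost its call without any 1 of 6 arrays (adjusted p up to 0.071, without replicate B of WT at 16C), and AT5G52790 without any 1 of 6 and AT5G16230 without any 1 of 7 (both up to 0.098, without replicate C of WT at 16C). AT5G33370 lost it without any 1 of 6 (up to 0.095, without replicate B of WT at 16C) and AT4G15120 without any 1 of 10 (up to 0.123, without replicate B of WT at 23C). AT1G43590 and AT5G52790 had 0.0552 each and AT4G15120 0.0703 with the letters as replicate block. Groups of 3 arrays did not overlap for 12.8% of probe sets, where chance gives 10%.

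Averaged over both temperatures, 6 arrays against 6, PDF1.2 (log2 change -3.58, SE 0.45, limma adjusted p = 0.048) and PDF1.2b (-4.20, SE 0.50, limma adjusted p = 0.047) fell. AT1G43590 (-2.60, SE 0.15, limma adjusted p = 0.00033), AT5G33370 (-2.27, SE 0.24, limma adjusted p = 0.020), AT4G01390 (-2.22, SE 0.29, limma adjusted p = 0.0497) and AT3G22540 (-1.84, SE 0.17, limma adjusted p = 0.010) fell too. The unnamed 255725_at rose by 3.93 (SE 0.16, limma adjusted p = 2.4e-05) and was the 1 probe set called up of 13. The 12 called down also held SAG29, with a log2 change of -0.78 (SE 0.10), AT5G57170, AT2G03140 and AT5G55720, all named outside the rule for this comparison. The unnamed 254806_at and 266383_at were called down too, and 266383_at fell by 2.83 (SE 0.35). The call of 254806_at was the least stable of these, as it was lost without any 1 of 12 arrays. SAG29 and AT5G33370 had at least 1 pft1-1 group mean under 2.52, near background, so their falls are lower bounds. The jasmonate-ethylene defence list again ranked low (camera adjusted p = 0.0055, and adjusted p = 0.473 with an estimated correlation), with 2 of 4 members fallen both over all probe sets and adjusted over the list alone. Without replicate A of pft1-1 at 16C its adjusted p was 0.0661.

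For this average, 1419 probe sets had an unadjusted p under 0.05. With the letters as replicate block 12 were called. Of the 9 called probe sets followed through the settings 5 lost their calls there. Among these were PDF1.2 (limma adjusted p = 0.102), PDF1.2b (0.0948), AT4G01390 (0.10) and 266383_at (0.0948). Letter C as a block left 8, and 5 of the 9 lost their calls. Among these were PDF1.2 (limma adjusted p = 0.0755), PDF1.2b (0.0704), AT4G01390 (0.0755) and 266383_at (0.0755). Letters A and B alone left 1 and renewed quantile normalisation 8. The count was 6, 8 and 8 without replicates A, B and C of WT at 16C, 22 and 5 without replicates A and C of WT at 23C, 22 without replicate A or C of pft1-1 at 16C, and 3 and 7 without replicates A and C of pft1-1 at 23C. PDF1.2 lost its call without any 1 of 11 arrays and PDF1.2b without any 1 of 9 (both up to 0.120, without replicate C of pft1-1 at 23C). AT4G01390 lost it without any 1 of 10 (up to 0.156, without replicate C of WT at 16C), 266383_at without any 1 of 9 (up to 0.149, without replicate A of pft1-1 at 23C), AT5G33370 without any 1 of 5 (up to 0.089, without replicate C of pft1-1 at 23C) and AT3G22540 without replicate A of pft1-1 at 23C (0.051).

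The study concerns flowering, and few flowering genes had a named probe set. GI, a clock and photoperiod gene, averaged 7.04 ± 0.34 (SD, n = 3) in WT and 7.66 ± 0.28 (SD, n = 3) in pft1-1 at 23C, a log2 difference of 0.62 (SE 0.24) that did not pass (limma adjusted p = 0.605). At 16C GI averaged 7.46 ± 0.14 (SD, n = 3) in WT and 7.40 ± 0.42 (SD, n = 3) in pft1-1, a difference of -0.06 (SE 0.24, limma adjusted p = 1.0). The flowering promoters AGL24, GI and FD and the repressors SMZ, SNZ and AT1G69570 gave 0 calls in limma in any comparison, over all probe sets or over the list alone. FD averaged under 2.52 in every group and AGL24 in all but WT at 23C, near background, where a fall cannot be seen. CO, FT, TSF, SOC1, FLC, SVP and TEM1 had no named probe set in the annotation used and were not analysed here. Of 6 measured Mediator subunit genes 0 were called between genotypes, and MED19A rose with temperature in WT (log2 change 0.83, SE 0.17, limma adjusted p = 0.031) and in pft1-1 (log2 change 0.97, SE 0.17, limma adjusted p = 0.0065).

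The comparison of 23C with 16C in WT gives the background difference between growth temperatures, called the temperature response here. All seedlings were 10 days old, and the labels give no developmental stage. A direct response to temperature therefore cannot be told apart from a difference in stage. Among probe sets with 1 gene and groups that do not overlap, the largest falls at 23C were in AT4G30170 (log2 change -5.24, SE 0.56, limma adjusted p = 0.0020), the defensin-like PDF2.5 (-5.02, SE 0.29, limma adjusted p = 4.4e-05), AT5G62210 (-4.42, SE 0.49) and AT5G09480 (-4.40, SE 0.64). SBT4.12, a subtilisin-like protease gene (-4.21, SE 0.16), and GSTU25, a glutathione S-transferase gene (-4.12, SE 0.58), fell strongly. PDF1.2b and PDF1.2 rose by 4.49 (SE 0.71, limma adjusted p = 0.011) and 4.19 (SE 0.63, limma adjusted p = 0.0094). Other genes that rose included AT5G51440 (2.71 to 2.74 on the WT arrays at 16C and 5.88 to 6.56 at 23C) and AT2G07777 (3.25, SE 0.45). Among them were also ccb452, a cytochrome c biogenesis gene of the mitochondrial genome (3.05, SE 0.53), and AT3G28270 (2.71, SE 0.31). AT2G07777 averaged under 2.52 at 16C, near background, so its rise is a lower bound. Without replicate A of WT at 23C the adjusted p of ccb452 was 0.057. Each of these genes had 3 arrays at 23C on 1 side of the 3 arrays at 16C, which the rule for naming them required.

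By gene group, the cold-responsive list had 1 of 6 members fallen in WT, over all probe sets and adjusted over the list alone: LTI30, a cold-induced dehydrin gene, dropped by 3.39 (SE 0.44, limma adjusted p = 0.0049). Of 12 glutathione S-transferase genes 3 fell, GSTU25, GSTU22 (-2.94, SE 0.37) and GSTU26 (-2.60, SE 0.57), and adjusted over the list alone 3 fell and 1 rose. Of 9 peroxidase genes 2 fell by either count, AT5G66390 (-2.74, SE 0.50) and Prx37 (-2.44, SE 0.36). The root hair genes EXPA7, EXPA18 and AT4G26010 had log2 changes of -1.24 (SE 0.93), -1.73 (SE 0.81) and -3.10 (SE 1.19), all negative, with 0 of 3 called by either count (camera adjusted p = 0.0753). All 3 averaged under 2.52 at 23C, near background, so the size of these changes is uncertain. EXPA7 stood at 5.42, 2.04 and 2.34 on replicates A, B and C of WT at 16C. The cell cycle genes ranked low as a list (camera adjusted p = 0.0059, and adjusted p = 0.355 with an estimated correlation). Among them AUR2, an Aurora kinase gene, fell by 1.64 (SE 0.32, limma adjusted p = 0.024), 1 of 3 members over all probe sets and 3 of 3 adjusted over the list alone. The flavonoid and anthocyanin list also ranked low (camera adjusted p = 0.0057, and adjusted p = 0.355 with an estimated correlation), with 0 of 5 members called over all probe sets and 3 fallen adjusted over the list alone. Of 9 xyloglucan endotransglucosylase genes, which remodel cell walls, XTH19 fell by 1.54 (SE 0.36, limma adjusted p = 0.044), and adjusted over the list alone 4 fell and 1 rose (camera adjusted p = 0.047, and adjusted p = 0.355 with an estimated correlation). Of 24 cytochrome P450 genes 2 rose, CYP71B24 (1.87, SE 0.36) and CYP71B5 (1.49, SE 0.34), and 5 rose adjusted over the list alone. Adjusted over each list alone, 2 iron deficiency genes and 1 heat shock gene rose, and 1 pentatricopeptide gene fell, with 0 called over all probe sets in limma.

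Some of these WT results rested on single arrays. AT5G66390 had an adjusted p of 0.072 without replicate B of WT at 16C. AUR2 had 0.091 and 0.090 without replicates B and C of WT at 16C, and 0.068 and 0.067 without replicates A and B of WT at 23C. CYP71B24 had 0.088 without replicate B of WT at 16C and 0.070 without replicate A of WT at 23C. CYP71B5, GSTU26, MED19A and XTH19 lost their calls without any 1 of several arrays, with adjusted p up to 0.144 for CYP71B5 and 0.115 for GSTU26 (both without replicate B of WT at 16C), and up to 0.103 for MED19A and 0.141 for XTH19 (both without replicate A of WT at 23C). The xyloglucan endotransglucosylase list had an adjusted p of 0.239 without replicate A of WT at 16C, 0.149 without replicate C of WT at 23C, 0.0572 and 0.0512 without replicates A and B of pft1-1 at 23C, and 0.0548 with the letters as replicate block. In letters A and B alone the adjusted p was 0.011 for the cell cycle, 0.019 for flavonoids and 0.036 for this list, and 13 of the 34 named genes kept their calls. PDF1.2 (limma adjusted p = 0.116) and PDF1.2b (limma adjusted p = 0.0921) did not. Letter C as a block kept all 34.

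In all, 1112 probe sets were called in WT, 395 up and 717 down (64.5% down), of which 673 changed by at least 1 on the log2 scale. Arrays of a letter shared variation here, and with the letters as replicate block 1859 were called. Letter C as a block gave 1704, letters A and B alone 481, only the 6 WT arrays 348, and array quality weights 4295. The count was 381 and 443 without replicates B and C of WT at 16C, 453 and 636 without replicates A and B of WT at 23C, and 692 without replicate B of pft1-1 at 16C. Centring arrays on their medians moved the split to 579 up and 672 down (53.7% down). Groups of 3 arrays did not overlap for 26.0% of probe sets, where chance gives 10%.

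The same comparison in pft1-1 gave the response of the mutant. Among probe sets with 1 gene and groups that do not overlap, the largest falls were in AT2G43590 (log2 change -7.22, SE 0.52, limma adjusted p = 0.00017), GSTU25 (-6.03, SE 0.58), AT1G18980 (-5.41, SE 0.18), AT5G59330 (-5.32, SE 0.51) and AT1G73620 (-5.32, SE 0.79). AT2G05540 rose by 5.72 (SE 0.62, limma adjusted p = 0.0011), AT1G62510 by 4.96 (SE 0.98), AT1G19530 by 4.81 (SE 0.83) and HIS1-3, a linker histone gene, by 4.65 (SE 0.47). BHLH101, a transcription factor gene of the iron deficiency response, rose by 4.50 (SE 1.04, limma adjusted p = 0.018). Both measured iron deficiency genes rose by either count, BHLH101 and PYE (1.37, SE 0.32). BHLH101 averaged under 2.52 in pft1-1 at 16C, near background, so its rise is a lower bound. PDF1.2 and PDF1.2b had log2 changes of 0.08 (SE 0.63) and -0.96 (SE 0.71) and did not pass.

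Genes of the cell cycle fell together at 23C in pft1-1. All 3 measured members fell by either count: AUR1 (-3.90, SE 0.73), AUR2 (-2.08, SE 0.32) and PRL, a DNA replication factor gene (-1.67, SE 0.33), with a camera adjusted p = 0.0042 (adjusted p = 0.268 with an estimated correlation). In the flavonoid and anthocyanin list 4 of 5 fell over all probe sets and 5 adjusted over the list alone, among them DFR (-5.30, SE 1.09, limma adjusted p = 0.012), UF3GT (-4.06, SE 0.90) and AT4G14090 (-4.01, SE 0.67), with a camera adjusted p = 0.0031 (adjusted p = 0.290 with an estimated correlation). DFR and UF3GT averaged 2.46 and 2.46 in pft1-1 at 23C, near background, so their falls are lower bounds. In the glucosinolate list 2 of 3 fell by either count, BCAT4 (-3.94, SE 0.88) and GSTU20 (-3.69, SE 0.68), with a camera adjusted p = 0.016 (adjusted p = 0.337 with an estimated correlation). In the cold-responsive list 3 of 6 fell and 1 rose by either count. LTI30 (-3.40, SE 0.44), COR15A, a chloroplast cold-protection gene (-3.38, SE 0.61), and COR15B (-2.41, SE 0.64) fell, while AT4G33980 rose by 1.07 (SE 0.32).

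In the peroxidase, cell wall and glutathione S-transferase lists some members fell, and in all but the peroxidases most were not called. Of 9 peroxidase genes 5 fell by either count, led by AT5G66390 (-3.80, SE 0.50) and Prx37 (-3.16, SE 0.36), with a camera adjusted p = 0.014 (adjusted p = 0.252 with an estimated correlation). Of 9 xyloglucan endotransglucosylase genes 2 fell and 1 rose by either count, XTH19 (-4.83, SE 0.36), XTH20 (-3.18, SE 0.40) and EXGT-A3 (1.40, SE 0.36), with a camera adjusted p = 0.016 (adjusted p = 0.268 with an estimated correlation). XTH20 averaged 2.46 in pft1-1 at 23C, so its fall is a lower bound. Of 19 expansin genes 3 fell by either count, EXPB3 (-3.02, SE 0.76), EXPB1 (-2.03, SE 0.44) and EXLA2 (-0.63, SE 0.15), with a camera adjusted p = 0.019 (adjusted p = 0.290 with an estimated correlation). Of 12 glutathione S-transferase genes 4 fell and 1 rose by either count, with a camera adjusted p = 0.016 (adjusted p = 0.268 with an estimated correlation), and GSTU20 is also in the glucosinolate list. Renewed quantile normalisation raised the number of negative expansin members from 11 to 15 and kept the median negative in each of these lists, as centring on array medians did. Other called genes were OSM34 (-2.57, SE 0.43), OPCL1 of jasmonate synthesis (-1.20, SE 0.21), PPR596 (-1.27, SE 0.24), the heat shock list member AT5G48570 (2.45, SE 0.55) and 4 of 24 cytochrome P450 genes, all up by either count. OSM34 was 1 of 4 jasmonate-ethylene genes called, OPCL1 1 of 2 jasmonate synthesis genes and PPR596 1 of 2 pentatricopeptide genes, by either count. AT5G48570 was 1 of 4 heat shock genes, and 2 rose adjusted over the list alone. Of the markers of other tissues, 1 of 3 root marker genes fell by either count, PYK10 (-0.93, SE 0.26, limma adjusted p = 0.040). The root hair genes EXPA7, EXPA18 and AT4G26010 had log2 changes of -1.77, -1.92 and -3.47 that did not pass. Their size is uncertain, as all 3 averaged under 2.52 at 23C, near background.

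Among these pft1-1 results, PYK10 had an adjusted p of 0.129 and 0.103 without replicates A and B of pft1-1 at 16C, and 0.098 and 0.119 without replicates A and C of pft1-1 at 23C, 0.051, 0.057 and 0.059 without replicates A, B and C of WT at 16C, and 0.0503 without replicate C of WT at 23C. BCAT4 had 0.053 without replicate A of pft1-1 at 16C. COR15B had 0.102, 0.065 and 0.060 without replicates A, B and C of pft1-1 at 16C, and 0.092 and 0.098 without replicates A and C of pft1-1 at 23C. BHLH101 had 0.0502 and 0.053 without replicates A and B of pft1-1 at 16C, and 0.059 and 0.055 without replicates A and C of pft1-1 at 23C, and PYE 0.058 and 0.063 without the latter arrays. AT5G48570 had 0.053 without replicate A of pft1-1 at 16C and 0.060 without replicate A of pft1-1 at 23C. EXPB3, EXLA2, EXGT-A3 and AT4G33980 also lost their calls without any 1 of several arrays, with adjusted p up to 0.085, 0.067 and 0.153 for EXPB3, EXLA2 and AT4G33980 (without replicate A of pft1-1 at 16C) and 0.092 for EXGT-A3 (without replicate A of pft1-1 at 23C), and EXPB1 had 0.0504 without replicate C of pft1-1 at 23C. AT4G33980 had 0.0573 with the letters as replicate block. The expansin list had 0.0573 without replicate A of pft1-1 at 16C. Of the 46 named genes 25 kept their calls in letters A and B alone, and the 7 lists that passed had camera adjusted p from 0.0065 to 0.0192. With letter C as a block all 46 were kept.

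In pft1-1, 4023 probe sets were called, 1914 up and 2109 down (52.4% down), of which 2307 changed by at least 1 on the log2 scale. With the letters as replicate block 5167 were called, with letter C as a block 5197, and in letters A and B alone 2334. The count was 2499 without replicate A of pft1-1 at 16C and 2483 without replicate A of pft1-1 at 23C. Centring arrays on their medians moved the median change over all probe sets by 0.10 and the split to 2650 up and 1948 down (42.4% down), so the larger share of falls turned into a larger share of rises relative to the array medians. The changes in the called genes named above for this comparison were larger than this shift, while that of PDF1.2, which was not called, was smaller. Groups of 3 arrays did not overlap for 47.9% of probe sets, where chance gives 10%.

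The temperature responses of both genotypes ran in the same direction for most genes called in WT, while most genes called in pft1-1 were not called in WT. Of the 1112 probe sets called in WT, 950 were called in the same direction in pft1-1 (85.4% of the WT calls and 24% of the pft1-1 calls), 324 up against 33.2 from chance and 626 down against 66.5 from chance, and 1 was called in opposite directions. Across all probe sets, which are not independent replicates, the changes correlated with Pearson 0.836 and Spearman 0.734. Shared genes include GSTU25, PDF2.5, LTI30, XTH19 and CYP71B24. Sizes were compared, in a test chosen after the results were seen, on the 5393 probe sets called for the temperature change averaged over both genotypes. This choice treats both genotypes alike, but it can enlarge the change in the genotype whose arrays vary more. Their median change was 0.66 in WT and 0.96 in pft1-1 in absolute log2 units, and the median ratio of the pft1-1 to the WT change was 1.497 for rises and 1.39 for falls. In letters A and B alone, on 4324 probe sets, the ratios were 1.34 and 1.198. Over the probe sets called in WT, a choice that favours WT, the medians were 1.2 in WT and 1.26 in pft1-1. The count of shared calls was 1599 with the letters as replicate block, 1450 with letter C as a block and 414 in letters A and B alone. It was 337 and 383 without replicates B and C of WT at 16C, 391 and 535 without replicates A and B of WT at 23C, 570 without replicate B of pft1-1 at 16C and 617 without replicate A of pft1-1 at 23C.

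**Figure D3:**
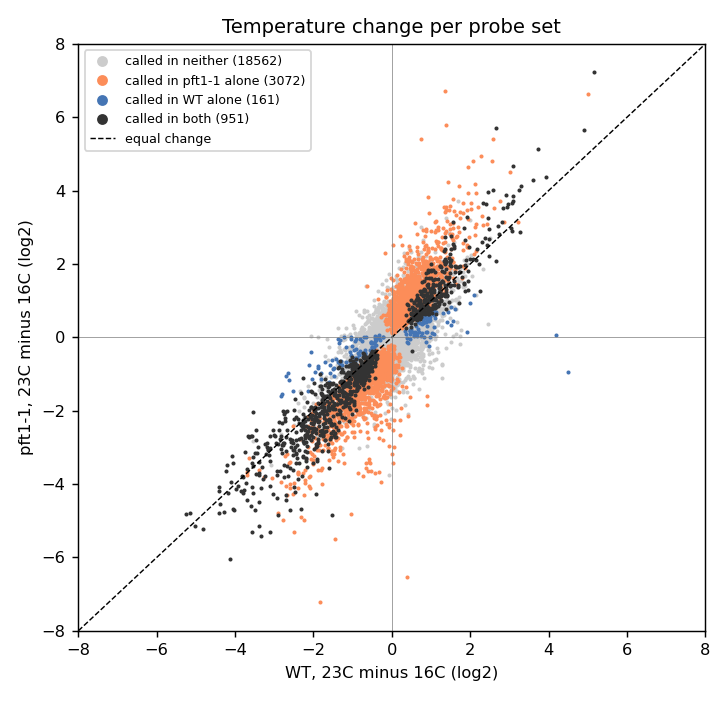
Each point is 1 of 22746 probe sets, with the 23C minus 16C change (log2) in WT on the horizontal axis and in pft1-1 on the vertical axis. Colours give the comparison in which a probe set was called, and the dashed line marks equal change. The 950 probe sets called in the same direction in both genotypes lie in the lower left and upper right of the plot, and the Pearson correlation across all probe sets was 0.836.

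Between the genotype comparisons, 2 of the 5 probe sets called at 23C were also called at 16C in the same direction and 0 in opposite directions. These were the unnamed 255725_at up and AT1G43590 down, where chance gives 0.00018 and 0.00070. Across all probe sets, most of them not called, the changes correlated with Pearson 0.07 and Spearman 0.01, which does not show that the effects differ. AT1G43590 averaged 4.99 ± 0.31 and 5.73 ± 0.36 in WT at 16C and 23C, and 2.61 ± 0.02 and 2.91 ± 0.27 in pft1-1 (SD, n = 3 each). With the letters as replicate block 1 probe set was shared, AT1G43590 then having an adjusted p of 0.0552 at 16C, and in letters A and B alone 1.

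The interaction asked directly whether the difference between pft1-1 and WT changes between temperatures. The jasmonate-ethylene defence list had negative differences, 23C minus 16C, of the pft1-1 effect: PDF1.2b -5.45 (SE 1.00), PDF1.2 -4.11 (SE 0.89), OSM34 -1.55 (SE 0.60) and PDF1.1, listed as LCR67, -0.42 (SE 0.30). As a list they ranked low (camera adjusted p = 5.5e-06, and adjusted p = 0.0858 with an estimated correlation), with 0 of 4 called over all probe sets and 3, all but PDF1.1, lower adjusted over the list alone. The glucosinolate genes BCAT4 (-3.67, SE 1.24), GSTU20 (-2.82, SE 0.96) and UGT74B1 (-1.64, SE 0.55) also ranked low (camera adjusted p = 0.00023, and adjusted p = 0.219 with an estimated correlation), with 0 of 3 called over all probe sets and 3 lower adjusted over the list alone. The 9 peroxidase genes had a median difference of -0.71 (camera adjusted p = 0.046, and adjusted p = 0.219 with an estimated correlation), with 0 called by either count. XTH19 was the 1 xyloglucan endotransglucosylase gene lower adjusted over the list alone, at -3.29 (SE 0.50), and OPCL1 the 1 jasmonate synthesis gene, at -1.35 (SE 0.30).

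No single probe set passed the interaction in limma (0 called, smallest adjusted p 0.237), and 0 passed in every other planned setting that used all 12 arrays. An unadjusted p under 0.05 was found for 1259 of 22746 probe sets, close to the share of 0.05 that chance gives. Without replicate A of pft1-1 at 16C or replicate B of pft1-1 at 23C 6 were called, without replicate B or C of pft1-1 at 16C 2, and without replicate C of WT at 16C or of pft1-1 at 23C 1. Camera passed 6 lists with the letters as replicate block, these 3 among them. In letters A and B alone the camera adjusted p was 0.00623 for the jasmonate-ethylene list, 0.0124 for glucosinolates and 0.110 for peroxidases. The peroxidase list had 0.101 and 0.124 without replicates B and C of WT at 16C, 0.0877 without replicate B of WT at 23C, 0.0669 without replicate A of pft1-1 at 16C, and 0.0856 and 0.0777 without replicates A and C of pft1-1 at 23C.

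The remaining lists gave 0 calls over all probe sets in every comparison in limma and no camera call: salicylate defence, gibberellin synthesis and response, photosynthesis, WRKY and root hair genes. Of the lists too small for a set test, ethylene signalling gave 0 calls and shade and warm-temperature elongation gave 0, with 1 ethylene gene up at 23C in pft1-1 adjusted over the list alone and 1 elongation gene up with temperature in pft1-1 on the same count. The reference genes AT4G34270 and PEX4 gave 0 calls over all probe sets, while 1 of these 2, PEX4, rose in pft1-1 at 23C (log2 change 0.41, SE 0.10) and in the average (0.32, SE 0.07) adjusted over the list alone.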

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

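The tests of array quality weights, of splits that keep the letters, of the size of the temperature response and of the letter C arrays were chosen after the results they address had been seen.

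The difference between the genotype effects at 23C and 16C passed the set test for 3 lists, with mean log2 differences of -2.88 for jasmonate-ethylene defence, -2.71 for glucosinolate synthesis and -0.471 for peroxidases. With an estimated correlation none passed (camera adjusted p = 0.0858, 0.219 and 0.219), and with fry jasmonate-ethylene defence did (adjusted p = 0.025) and the others did not (adjusted p = 0.131 each). Splitting the arrays otherwise within each temperature gave at least 3 lists in 20 of 100 splits and up to 7, without regard to the letters. With the letters as replicate block 6 lists passed. Of 32 splits that keep the letters, the real one counted, 2 gave at least 6. The other of these, with 7, exchanged the genotypes in every pair but replicate A of 16C. Apart from its sign it differs from the real split in that pair only, so it is hardly a separate comparison. Chance cannot be excluded for the number of lists either way. For the count of probe sets the splits decide nothing, since the real count was 0 and all 100 of 100 and 32 of 32 splits are as large by construction. Poly-A spike-in probe sets, which the comparisons do not use, averaged 9.51 on the letter C array of pft1-1 at 16C and 8.68 on that of pft1-1 at 23C, above the highest WT array.

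The plant defensin genes PDF1.2 and PDF1.2b were lower in pft1-1 than in WT at 23C, by -6.28 on average on the log2 scale. A labelling difference of letter C as the whole source is argued against by the mean of -5.87 in letters A and B alone, where both pft1-1 arrays lay below both WT arrays for each gene. Low RNA quality of the letter C array of pft1-1 at 23C is argued against by the mean of -6.32 without it. Whether the difference reflects a rise in WT that the mutant lacks stays open: the mean change from 16C to 23C was 4.34 in WT and -0.44 in pft1-1, and neither gene passed the interaction over all probe sets, while both did adjusted over the list alone. A candidate explanation is that these genes need PFT1 for their higher level at 23C, a hypothesis found and tested on the same data, with adjusted p of 0.170 for PDF1.2 and 0.147 for PDF1.2b with the letters as replicate block.

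More probe sets were called for temperature in pft1-1 than in WT, 4023 against 1112, a ratio of 3.62. The letter C array of pft1-1 at 23C as the whole source is argued against by a ratio of 2.35 without it, and a labelling difference of letter C by a ratio of 4.85 in letters A and B. With array quality weights the ratio was 0.899, with 4295 calls in WT and 3862 in pft1-1, so unequal arrays may account for the excess of calls. The weights come from the spread of these same arrays within their groups. They therefore cannot tell poor quality of an array from biological spread. A larger response in the mutant stays open: on probe sets called for the average of both genotypes the smaller median ratio of change in letters A and B was 1.198, between the bounds set, and no probe set passed the interaction. Without single arrays these median ratios of change, for rises and for falls, ran from 1.21 to 1.96. Leaving out single arrays moved the ratio of the counts from 2.35 to 9.35, the highest without replicate A of WT at 23C, with 9.28 and 8.04 without replicates B and C of WT at 16C and 5.80 without replicate B of WT at 23C.

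The letter C arrays stood apart in all 4 groups. On the second principal component, which held 14.1% of the variance, 4 of 4 letter C arrays lay below every other array. No biological explanation was tested, as the labels give none that differs between letters. Their poly-A spike-in probe sets averaged 4.84 to 9.51, against 2.45 to 2.54 on the other arrays, so the spike-in content of these samples differed. Whether a difference in RNA or labelling accounts for the pattern stays open. The 3' minus 5' control difference of letter C was higher (exact permutation p = 0.00202, the smallest it can give), but this was seen together with the pattern and is no separate test of it. In addition 1485 probe sets differed between letter C and the others. What was done differently is not given in the labels.

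Other splits of the same arrays were counted for each comparison, and the shares of 10 and of 32 include the real split. With 10 splits of 6 arrays a share under 0.05 cannot be reached. At 23C the real split of the genotypes called 5 probe sets and the highest other 48 (3 of 10 as large), and 5 lists against 2 (1 of 10). At 16C it called 8 against 110 (2 of 10), and 1 list against 5 (8 of 10). For temperature in WT it called 1112 against 0 (1 of 10), and 3 lists against 4 (3 of 10). For temperature in pft1-1 it called 4023 against 1 (1 of 10), and 7 lists against 5 (1 of 10). For the genotype average 10 of 100 splits gave at least 13 calls, up to 348, and 52 of 100 gave at least 1 list, up to 7, so chance cannot be excluded for either count in splits that ignore the letters. The average had 12 calls with the letters as replicate block, and of the 32 splits that keep the letters the highest other had 1 (1 of 32 as large), which argues against chance for that count. The blocked average had 2 lists, and 10 of 32 such splits gave as many, up to 7, so chance cannot be excluded there. The splits with 48, 110 and 348 calls, and for the interaction 204, point to a structure among the arrays other than genotype. The split with 110 set both letter C arrays of 16C, with replicate B of WT, against the rest, and with letter C as a block the real split called 12, and in letters A and B alone 1. The split with 48 set replicate A of WT and replicates A and C of pft1-1 against the other arrays of 23C.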

How the results depend on the processing

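Letter C as a block, letter C alone and letters A and B alone were chosen after the data had been seen, and the other alternatives before. Of the called probe sets that an alternative fitted, 0 changed direction, while the upper 60% held only 2 of 8 at 16C, 10 of 13 for the average, 997 of 1112 in WT and 3616 of 4023 in pft1-1, and the share of falls among the calls in pft1-1 moved from 52.4% to 42.4% with centring on medians. The cause of a changed count was not tested, except that a stricter threshold, a minimum change or fewer arrays leaves fewer calls by construction. Counts are given in the order genotype at 23C, genotype at 16C, genotype average, temperature in WT, temperature in pft1-1, from 5, 8, 13, 1112 and 4023. Where a place is left out, the count stayed within 1.5 times. The replicate block gave 5 at 16C and 1859 in WT, with 1 shared genotype call and 1599 shared temperature calls (2 and 950 in the full model). The intensity trend gave 8 and 15 between genotypes, centring on medians 9 and 14, renewed quantile normalisation 8 for the average, and the upper 60% of probe sets 13 at 23C. Array quality weights gave 216 at 16C and 4295 in WT. Only the arrays compared gave 0, 0 and, in WT, 348, and could not be fitted for the average and the interaction, which need all groups. A minimum change gave 673 and 2307 for temperature, and an adjusted p under 0.01 gave 2, 3, 2, 229 and 1573, with 202 shared temperature calls. Letter C as a block gave 2 at 23C, 8 for the average and 1704 in WT, with 1450 shared. Letters A and B alone gave 2, 1, 1, 481 and 2334, with 1 and 414 shared. Letter C alone, additive in genotype and temperature, gave 0 for the average.

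Leaving out 1 array in turn gave 2 to 54, 3 to 42, 3 to 22, 381 to 1352 and 2483 to 4467 calls, 0 to 6 for the interaction, 2 to 3 shared genotype calls and 337 to 1178 shared temperature calls. The numbers of lists became 2 to 5, 0 to 3, 1 to 4, 2 to 6 and, for the interaction, 2 to 7, from 5, 1, 1, 3 and 3. The control 3' minus 5' differences became -0.37 to 0.60 at 23C, -0.51 to 0.012 at 16C, -0.41 to 0.19 in WT and -0.19 to 0.73 in pft1-1.

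Camera with an estimated correlation gave 0 lists in each comparison, and fry 1, 0, 9 and 11 at 23C, at 16C, in WT and in pft1-1, and 1 for the interaction. The replicate block gave 2 lists for the average and 6 for the interaction, the upper 60% 3 and 5, array quality weights 2 and 7 with 2 at 16C, letter C as a block 5 for the interaction, and letters A and B alone 2 at 23C and 2 for the average. Of the alternatives for named genes, 64 of 105 at 23C, 108 of 162 at 16C, 100 of 179 for the average, 599 of 714 in WT and 863 of 963 in pft1-1 kept the call. The signal over background limits genes whose group means lie under 2.52, the lower quartile of all values.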

Other observations

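The families formed from gene symbols, and all values in this part, were chosen after the annotation had been seen and were not planned. In pft1-1, 7 of 16 genes of the mitochondrial genome rose from 16C to 23C over all probe sets and 8 adjusted over the list alone (camera adjusted p = 0.023, and adjusted p = 0.757 with an estimated correlation). They included ccb452 (log2 change 2.98, SE 0.53), nad5 (2.67, SE 0.51), nad9 (2.53, SE 0.51) and cox2 (2.33, SE 0.60), genes of cytochrome c biogenesis and the respiratory chain. In WT nad9 (2.43, SE 0.51), ccb452 (3.05, SE 0.53) and nad4L (limma adjusted p = 0.045) rose. nad5 in pft1-1 and nad4L in WT averaged under 2.52 at 16C, near background, so their rises are lower bounds. Without replicate A of pft1-1 at 16C the camera adjusted p was 0.0686, and 0.0563 and 0.0815 without replicates A and C of pft1-1 at 23C. It was 0.063 in letters A and B alone and 0.0551 with letter C as a block.

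Photosynthesis genes of the plastid genome had lower values in pft1-1 than in WT at 16C. All 43 had a negative log2 change (median -0.42, camera adjusted p = 2.0e-06, and adjusted p = 0.952 with an estimated correlation), also under both other scalings, and 0 were called in limma. Examples are petG (-1.25, SE 0.34), petD (-1.10, SE 0.40) and psbB (-0.91, SE 0.41). Without replicate A of pft1-1 at 16C the adjusted p was 0.788, so the list rested on that array. The adjusted p was 1.4e-08 in letters A and B alone and 9.4e-08 with letter C as a block. Both of these settings keep that array and cannot show whether the list holds without it. The 19 plastid ribosomal and polymerase genes had a median of -0.44 (camera adjusted p = 0.038, and adjusted p = 0.952 with an estimated correlation), and 0.938 without the same array, 0.411 and 0.615 without replicates B and C of WT at 16C, 0.0572 without replicate B of pft1-1 at 16C and 0.0746 without replicate C of pft1-1 at 23C. At 23C 10 of 13 RNA editing factor genes (CRR and OTP) had a negative change between genotypes (median -0.35, camera adjusted p = 0.0024, and adjusted p = 0.430 with an estimated correlation), among them CRR21 (-0.90, SE 0.27) and OTP84 (-0.71, SE 0.23), with 0 called in limma. Without any single array the adjusted p stayed at or under 0.0458, it was 0.0040 with letter C as a block and 0.161 in letters A and B alone. Averaged over temperatures 12 of 13 were negative (camera adjusted p = 0.00089, and adjusted p = 0.348 with an estimated correlation), with 0.225 in letters A and B alone. At 23C all 10 autophagy genes of the ATG8 and ATG3 families had a positive change between genotypes (median 0.41, camera adjusted p = 0.0050, and adjusted p = 0.717 with an estimated correlation), with 0 called in limma. In letters A and B alone 1 of them was negative (adjusted p = 0.031), and the adjusted p was 0.150 and 0.0519 without replicates B and C of WT at 23C and 0.0929 without replicate A of pft1-1 at 23C. The other families that passed were the plastid photosynthesis genes (camera adjusted p = 9.4e-06, and adjusted p = 0.794 with an estimated correlation), the plastid ribosomal and polymerase genes (0.0058, and adjusted p = 0.794 with an estimated correlation) and the BGLU genes (0.039, and adjusted p = 0.348 with an estimated correlation) averaged over temperatures, and the tubulin genes at 16C (0.038, and adjusted p = 0.952 with an estimated correlation). Without single arrays the adjusted p rose to 0.191 and 0.310 for the plastid sets (without replicate A of pft1-1 at 16C), 0.175 for BGLU (without replicate C of pft1-1 at 16C) and 0.488 for tubulins (without replicate C of WT at 16C). With letter C as a block BGLU had 0.0637 and tubulins 0.0059, and in letters A and B alone 0.342 and 0.129.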
